A study of Mus musculus with 4 samples.

How the data were processed

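Bulk RNA sequencing was carried out on LSK cells sorted from mouse bone marrow. LSK cells are the lineage-negative, Sca1-positive and Kit-positive fraction that holds the hematopoietic stem cells and early multipotent progenitors. The mice were aged 13 to 15 months. There were 4 libraries, 2 from wild-type (WT) animals and 2 from animals heterozygous for the p53 mutation R248W (p53R248W/+), a missense change in the DNA-binding domain of the tumour suppressor p53. The groups and replicate numbers were taken from the sample labels. The labels do not say whether the replicates of a genotype came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

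The deposited table holds raw, unnormalised read counts per gene for the 4 libraries, made by the authors. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.7.10a, featureCounts from Subread 2.0.3 and edgeR 3.40.2 were used, and the genome build was mm10. Per the labels' protocols, RNA was isolated with column kits and made into standard mRNA libraries. Whether reads were counted by strand, and how reads with several alignments were treated, is not given in the sources used here. Overlapping genes and multi-copy genes are therefore uncertain. The deposited counts are given per gene symbol for 24421 genes, with exon coordinates in mm10. Each count column was matched to its sample by genotype and number in its name. No row lacked a gene name. The mitochondrially encoded genes, fixed as a further list, had 0 matched rows, so the mitochondrial share, a common sign of RNA quality, was not analysed here. Gene counts do not tell the alleles of Trp53 apart, so they cannot be used to check the genotype.

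Total counts were 14544290 and 14109906 in the WT libraries and 14820759 and 12111126 in the p53R248W/+ libraries. The 3-count detection floor corresponded to 0.202 to 0.248 CPM (counts scaled to a common library total), and it covers counting error only, since no source used here records molecular identifiers, and PCR copies are not independent molecules.

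All choices below were made before the data were examined, unless stated. Genes were filtered with filterByExpr at its default settings (minimum count 10, minimum total 15), which left 13296 genes. Libraries were scaled by TMM, and the genotypes were compared with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust=TRUE, glmQLFTest) in R 4.3.3, with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Fold changes are log2 values of p53R248W/+ over WT, each with its standard error (SE). CPM values use the TMM-scaled library sizes, and SDs are over the 2 libraries of a genotype.

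Of 28 gene lists fixed from textbook knowledge, 26 had at least 5 tested members apart from the sex-linked check genes. They covered p53 targets, stem cell identity and ageing, blood lineages and other cell types of the marrow, the cell cycle, histones, interferon and inflammation, inflammasomes, immediate early genes, chromatin, splicing, DNA repair, apoptosis, energy metabolism and ribosomal proteins. Each was compared with the other genes by camera (limma 3.58.1), two-sided, with the inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the 26 lists. An estimated correlation and the self-contained test fry were run beside it. Members were also adjusted over their list alone, which does not correct for the number of lists. List members not matched by symbol, and so not analysed here, were Ighm, Igha, Igkc, Ighg2c, Iglc2, Trbc1 and Trbc2.

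Genes were to be named where they passed the threshold, with a mean of at least 5 CPM and no overlap between genotypes, up to 10 per direction. No gene passed, so only Trp53, Cdkn1a, Mdm2, Ccng1 and Bax were named by that rule. All other genes in the text were chosen after their values were seen. The first were the 10 with the smallest unadjusted p meeting the same level and overlap criteria. Up to 4 members at an unadjusted p under 0.05 of each list that passed were added. Further list members given as values, and the genes that DESeq2 called, were also named.

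The alternatives were median-ratio scaling, total-count scaling, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, the legacy quasi-likelihood method, robust=FALSE, no filter, a stricter filter (at least 1 CPM in 2 libraries and a mean of 5 CPM), the replicate number as a block, and each library left out in turn. One alternative, the p53 target list without Cdkn1a and Btg2, was added after the data were seen. For the closing section, and not among the choices fixed beforehand, smooth trends on exon length and GC content were fitted with mgcv 1.9.3, using the transcripts of GENCODE M21 for GC content.

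The test was tried on simulated counts with the real means, library sizes and trended dispersion of this comparison, over 13296 genes with 200 changed genes in each of 10 simulations. Of genes changed 2-fold, 16.8% were recovered, against 53.2% at 4-fold and 73.9% at 8-fold. At a mean of at least 20 CPM, recovery was 29.6% at 2-fold, 87.1% at 4-fold and 99.7% at 8-fold. Each gene was simulated exactly at the trend, with no spread of dispersion between genes, so recovery in the real data may be lower. False calls were 3.04% of all calls. With genes simulated as independent, camera called 1 of 255 unchanged lists. Because the simulation left out correlation between genes, that rate does not cover co-regulated lists.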

Results

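Messenger RNA was measured in LSK cells from aged WT and p53R248W/+ mice, with 2 libraries per genotype and 12111126 to 14820759 counted reads in each. Between 14446 and 15080 genes had at least 1 count per library. Over the 13296 tested genes, log2 CPM values correlated at r = 0.906 between the WT libraries and at r = 0.906 between the p53R248W/+ libraries. Across genotypes r ranged from 0.885 to 0.928, and the most similar pair was WT replicate 2 with p53R248W/+ replicate 2. These correlations are across genes, which are not independent replicates. The first principal component held 43.2% of the variance and set WT replicate 1 against p53R248W/+ replicate 1, with both replicates 2 between them. Xist was at 14859 to 16191 CPM and the Y-linked gene Ddx3y at no more than 1.26 CPM in all 4 libraries. Kit, which encodes the receptor used in the sort, was at 911 and 998 CPM in WT and at 1182 and 1105 CPM in p53R248W/+.

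The single comparison in the design asks which transcripts of aged LSK cells differ when a mutant p53 allele is present. Trp53, the gene that carries the mutation (mm10 chromosome 11, 69580359 to 69591873, plus strand, 11 exon blocks), was counted at 362 and 302 CPM in the WT libraries and at 245 and 332 CPM in the p53R248W/+ libraries. Its log2 fold change was -0.21 ± 0.19 (SE, n = 2 per genotype; adjusted p = 0.895, edgeR quasi-likelihood test), with a 95% interval from -0.60 to 0.19. Without p53R248W/+ replicate 1 the fold change was 0.0023, and without p53R248W/+ replicate 2 it was -0.44. Cdkn1a, the cell cycle inhibitor p21 and a classical p53 target (chromosome 17, 29090986 to 29100722), was at 74.3 and 39.9 CPM in WT against 16.8 and 15.6 CPM in p53R248W/+. That is 3.52-fold lower in the fit, a log2 fold change of -1.81 ± 0.44 (SE). It did not pass over all genes (adjusted p = 0.824, edgeR quasi-likelihood test) and passed when adjusted over the list alone (adjusted p = 0.0286). Among the other fixed genes, Mdm2, the ubiquitin ligase that degrades p53, had a log2 fold change of -0.06 ± 0.22 (SE). The values were 0.06 ± 0.19 for the cyclin gene Ccng1 and -0.41 ± 0.79 for the pro-apoptotic gene Bax, which was at 3.84 to 8.35 CPM. The 95% intervals ran from -0.52 to 0.39 for Mdm2, from -0.35 to 0.46 for Ccng1 and from -2.06 to 1.24 for Bax. The directions of Mdm2 and Ccng1 turned when single libraries were left out. The Bax value was -0.03 without p53R248W/+ replicate 1, -0.04 without WT replicate 2, -0.70 without WT replicate 1 and -0.83 without p53R248W/+ replicate 2.

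**Figure D1:**
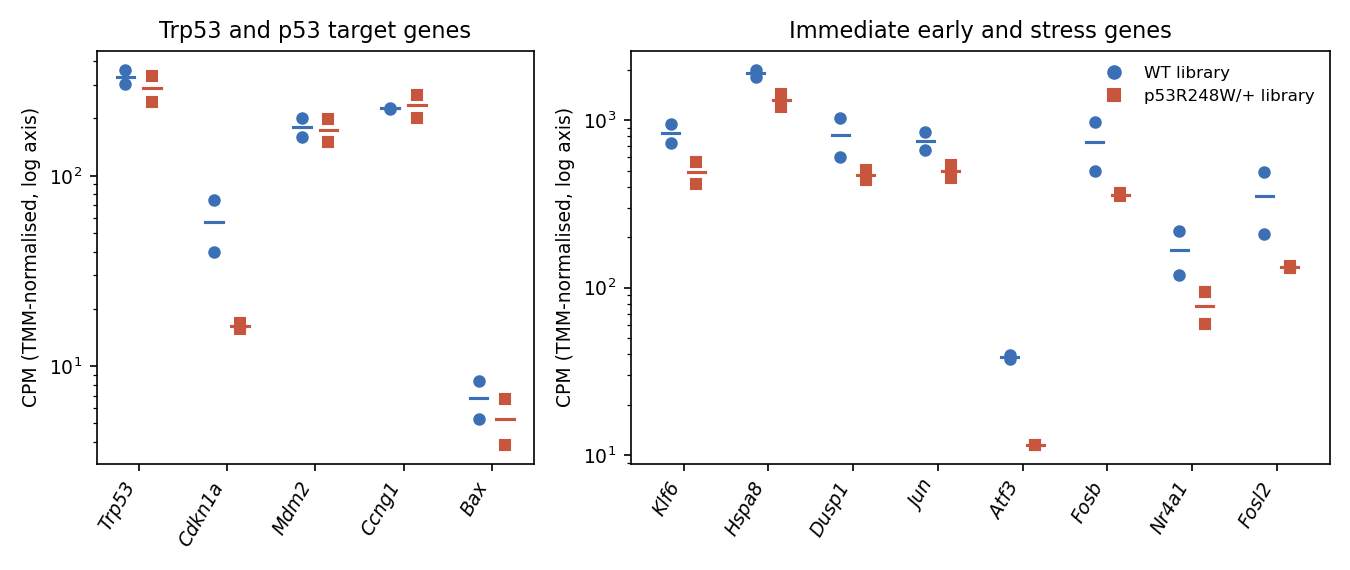
TMM-normalised CPM on a log axis for Trp53 and 4 p53 target genes (left) and for 8 immediate early and stress genes (right). Circles are the 2 WT libraries, squares the 2 p53R248W/+ libraries and bars the genotype means; Cdkn1a was at 74.3 and 39.9 CPM in WT against 16.8 and 15.6 CPM in p53R248W/+, and the 8 genes on the right were higher in both WT libraries than in either p53R248W/+ library.

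No gene passed the threshold in either direction: 0 were higher and 0 lower with edgeR's quasi-likelihood test, and the smallest adjusted p was 0.824. At an unadjusted p under 0.05 there were 780 genes, 400 higher and 380 lower, where 664.8 are expected by chance at the nominal rate and 725.2 at the rate of unchanged genes in simulated data. There were 414 such genes without WT replicate 1, 1083 without WT replicate 2, 336 without p53R248W/+ replicate 1 and 899 without p53R248W/+ replicate 2. limma-voom also called 0 genes. The likelihood ratio test of edgeR called 4, 3 higher and 1 lower, and DESeq2 called 7, 4 higher and 3 lower. The DESeq2 calls were Usp33, Il1rl1, Snora30 and Ddit4l higher and Fosl2, Cdkn1a and Mif4gd lower. The libraries of the genotypes did not overlap for 4462 genes, or 33.6% of those tested, where chance gives 33.3%. The biological coefficient of variation was 46.0%, so many 2-fold changes would go undetected with 2 libraries per genotype.

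The genes with the smallest unadjusted p included the immediate early and stress genes Klf6, Hspa8 and Dusp1, and none of them passed after adjustment (adjusted p = 0.824 for each, edgeR quasi-likelihood test). Among those higher in both p53R248W/+ libraries, Dntt, the template-independent DNA polymerase of early lymphoid progenitors, was at 93.3 and 114 CPM in WT against 155 and 284 CPM, with a log2 fold change of 1.07 ± 0.26 (SE) that was 0.58 without p53R248W/+ replicate 2. Il1rl1, the interleukin-33 receptor, was at 0.697 and 1.33 CPM in WT against 15.6 and 11.7 CPM. Pkhd1l1 was at 15.5 and 30.7 CPM in WT and at 65.4 and 68.6 CPM in p53R248W/+. Stam2, an endosomal sorting adaptor, was at 19.7 and 34.7 CPM in WT and at 74.7 and 70.4 CPM in p53R248W/+. Among those lower, the tRNA methyltransferase subunit Trmt61a was at 72.7 and 61.4 CPM in WT against 9.78 and 28.6 CPM, and Gatm, the first enzyme of creatine synthesis, was at 70.2 and 63.9 against 23.5 and 28.2 CPM. Cdkn1a completed the 10.

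Of the 26 gene lists tested, 10 passed camera with the preset correlation, 8 lower and 2 higher in p53R248W/+ than the other genes. None passed with an estimated correlation, and none passed the self-contained test fry, in its directional or its mixed form. The calls below therefore rest on the preset form of camera. For the p53 target, oxidative phosphorylation and histone lists the estimated correlations were 0.0043, -0.018 and -0.0023, under the preset 0.01. Their unadjusted camera p still rose, from 0.0112, 0.0111 and 0.00129 to 0.109, 0.0919 and 0.0638. The size of the correlation alone therefore does not account for the loss of those calls. Without p53R248W/+ replicate 1, the p53 target, B cell, replication, mitosis, histone and oxidative phosphorylation lists no longer passed. The lymphoid priming and ribosomal protein lists, which are outside the 10, passed in that fit.

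**Figure D2:**
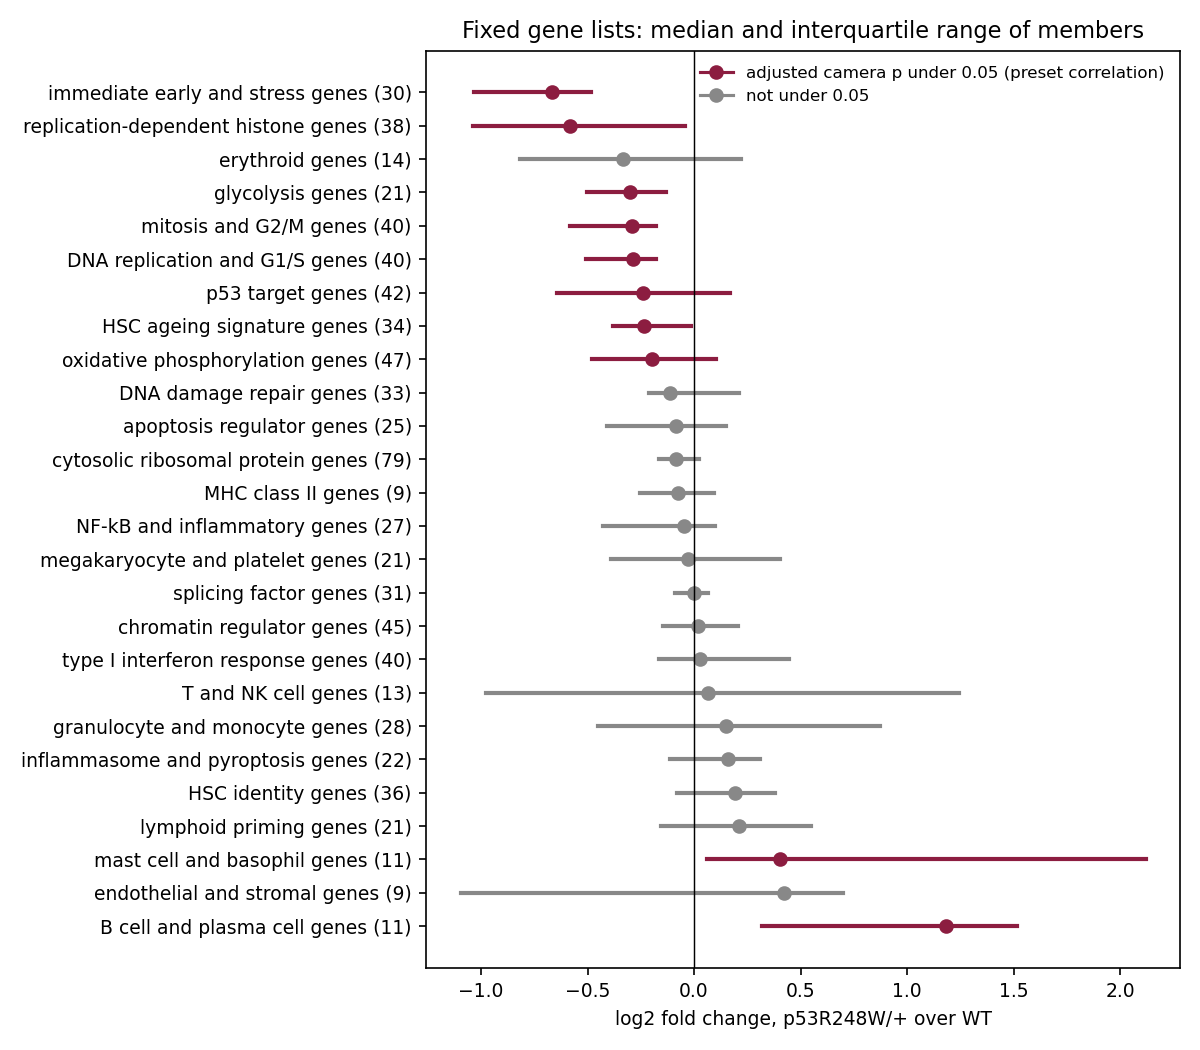
Log2 fold change of p53R248W/+ over WT for the 26 gene lists, with the number of tested members in brackets. Points are medians and lines the interquartile range of members, dark red where the adjusted camera p with the preset correlation was under 0.05; the immediate early and stress genes had the lowest median, -0.67, and the B cell and plasma cell genes the highest, 1.18.

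Immediate early and stress genes, which respond within minutes to growth factors, stress and cell handling, were lower in p53R248W/+ cells. Of the 30 tested members, 29 had a negative log2 fold change, with a median of -0.67, and 22 were lower in both p53R248W/+ libraries than in either WT library. The list passed camera at an adjusted p of 1.44e-18. With an estimated correlation its camera p was 0.0359 unadjusted and 0.657 adjusted, a value that the adjustment gave to several lists alike. No member passed over all genes and 8 passed when adjusted over the list alone, all lower. These were the transcription factor genes Klf6, Jun, Atf3, Fosb, Nr4a1 and Fosl2, the MAP kinase phosphatase Dusp1 and the heat shock cognate Hspa8, at adjusted p of 0.00671 to 0.00868 in the edgeR quasi-likelihood test. Klf6 (chromosome 13, 5861489 to 5870393) was at 839 ± 158 CPM in WT and 490 ± 102 CPM in p53R248W/+ (SD, n = 2), a log2 fold change of -0.78 ± 0.17 (SE). Atf3, a stress-induced factor, was at 38.5 ± 1.24 against 11.5 ± 0.0372 CPM, or -1.74 ± 0.47 (SE) on the log2 scale. Fosb was at 738 ± 336 against 359 ± 10.7 CPM and Fosl2 at 350.1 ± 199.8 against 133 ± 2.47 CPM. The WT replicates differed for several members, with Fosl2 at 491 and 209 CPM and Dusp1 at 1032 and 605 CPM. The list passed without each library in turn, and its median was -0.45 without WT replicate 1. Without that library the log2 fold changes of Dusp1, Fosb, Fosl2 and Nr4a1 were -0.36, -0.48, -0.65 and -0.59, where the full fit gave -0.80, -1.04, -1.40 and -1.09. Hspa8 has near-identical retrocopies in the genome, so its count is less certain.

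p53 target genes were lower as a list in p53R248W/+ cells. Of 42 tested members 26 were lower and 16 higher, the median log2 fold change was -0.24, and no member passed over all genes. Cdkn1a alone passed when adjusted over the list alone. Sesn2, a stress-induced inhibitor of mTORC1 signalling, was at 9.35 and 14.7 CPM in WT and 4.99 and 4.79 CPM in p53R248W/+ (log2 fold change -1.29 ± 0.72, SE). Xpc, a nucleotide excision repair gene, lay in the other direction at 0.62 ± 0.31 (SE). Camera gave an adjusted p of 0.0292, against an adjusted p of 0.657 with an estimated correlation. The list no longer passed without Cdkn1a and Btg2 (adjusted p = 0.125), without WT replicate 2 (0.255, median -0.09), without p53R248W/+ replicate 1 (0.107, median -0.21), without p53R248W/+ replicate 2 (0.187, median -0.32) or with the stricter filter (0.141, median -0.14).

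Genes of DNA replication and mitosis and the replication-dependent histone genes were lower as lists. Of the 40 replication and G1/S genes, 34 were lower, with a median of -0.29. The replication ligase Lig1 was at 189 and 192 CPM in WT against 93.8 and 132 CPM (log2 fold change -0.76 ± 0.23, SE), with 116 of its exon bases shared with the gene 6330408A02Rik. Cdc45, a subunit of the replicative helicase, had a log2 fold change of -1.12 ± 0.42 and Mcm3, another subunit, of -0.50 ± 0.22 (SE). Rrm1, the large subunit of ribonucleotide reductase, had a log2 fold change of -0.50 ± 0.22 (SE), or -0.22 without p53R248W/+ replicate 1 and -0.81 without p53R248W/+ replicate 2. Of the 40 mitosis and G2/M genes, 32 were lower, also with a median of -0.29. Of 68 matched histone genes 38 were tested, at a low level (median of the mean CPM 4.16). Of these 38 histone genes, 28 were lower, with a median of -0.58. Many histone genes are near-identical copies, which makes single members such as Hist1h4d (-0.85 ± 0.36, SE) uncertain. No member of the 3 lists passed, over all genes or when adjusted over the list alone. The adjusted camera p was 2.43e-05 for replication, 6.92e-04 for mitosis and 0.00557 for histones, and with an estimated correlation the adjusted p was 0.657, 0.724 and 0.657. Without p53R248W/+ replicate 1 none of the 3 lists passed: the medians were -0.06 for replication (adjusted p = 0.364) and 0.12 for mitosis (0.346), while the histone median was -0.53 (0.121), close to that of all libraries. Without WT replicate 2 the mitosis list had a median of 0.06 (adjusted p = 0.989) and the histone list of -0.49 (0.105), and without p53R248W/+ replicate 2 the medians of the 3 lists were -0.55, -0.82 and -0.95. The mitosis median was -0.56 without WT replicate 1.

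**Figure D3:**
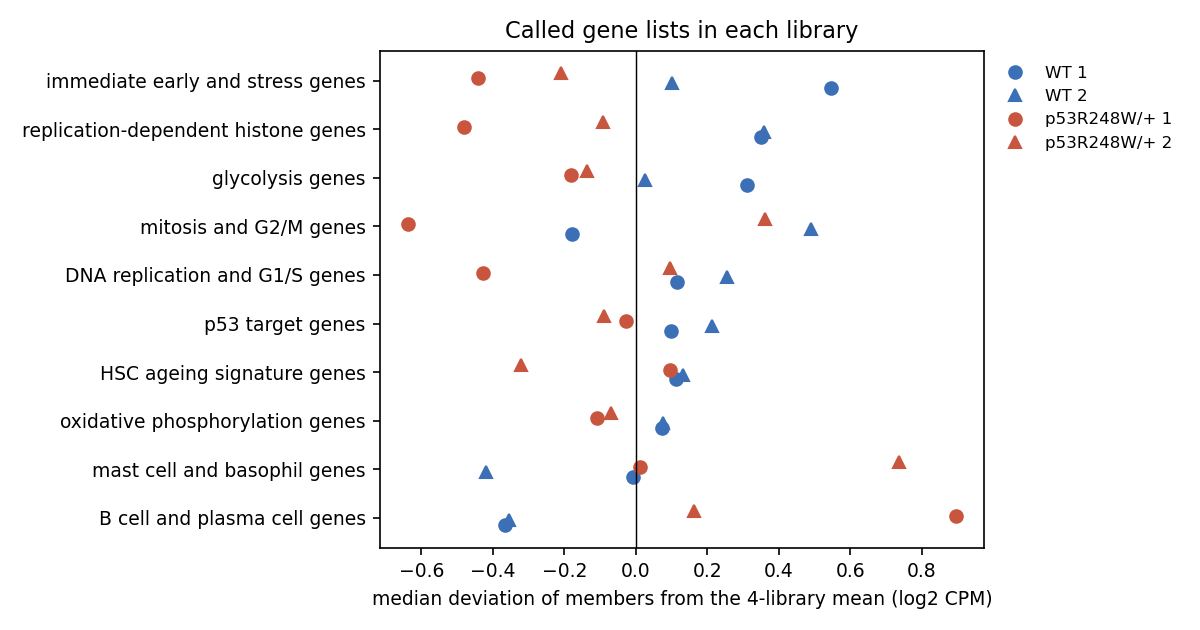
Median deviation of the members of each list that passed camera from the mean of the 4 libraries, in log2 CPM, for each library. Blue marks are WT and red marks p53R248W/+, with circles for replicate 1 and triangles for replicate 2. The mitosis list lay at -0.64 in p53R248W/+ replicate 1 and at 0.36 in p53R248W/+ replicate 2, and overlapped between genotypes. Every other plotted list separated the genotypes, some by little. WT replicate 1 and p53R248W/+ replicate 1 lay at 0.112 and 0.095 for the ageing list and at -0.009 and 0.013 for the mast cell list. For the replication list WT replicate 1 lay at 0.117 and p53R248W/+ replicate 2 at 0.097. The lists were plotted because camera called them for a genotype difference, so this separation is no further evidence.

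Genes of energy metabolism were lower as lists by small amounts. Of the 21 glycolysis genes, 18 were lower, with a median of -0.30. Hexokinase Hk2 was at 209 and 106 CPM in WT against 87.3 and 85.7 CPM (-0.86 ± 0.29, SE). Its log2 fold change was -0.30 without WT replicate 1. The log2 fold change was -1.04 ± 0.37 for Tpi1, which shares 25 exon bases with Spsb2, and -0.38 ± 0.15 for the lactate dehydrogenase gene Ldha, which was at -0.20 without p53R248W/+ replicate 2 and -0.60 without p53R248W/+ replicate 1. Of the 47 nuclear genes of oxidative phosphorylation, 32 were lower, with a median of -0.20. The ATP synthase genes Atp5a1 and Atp5b had log2 fold changes of -0.48 ± 0.17 and -0.30 ± 0.13 (SE). No member passed, over all genes or when adjusted over the list alone. Adjusted camera p was 0.00107 for glycolysis and 0.0292 for oxidative phosphorylation, and the adjusted p was 0.657 for both with an estimated correlation. Without WT replicate 1 neither list passed (medians -0.17 and -0.14, adjusted p = 0.114 and 0.219). The oxidative phosphorylation list also did not pass without p53R248W/+ replicate 1 (median -0.21, adjusted p = 0.121) or replicate 2 (median -0.25, 0.0940), although its median was no smaller, and the glycolysis median was -0.45 without WT replicate 2.

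Genes of the stem cell ageing signature, which rise in stem cells of old mice, were lower as a list in p53R248W/+ cells. Of 34 tested members 26 were lower, with a median of -0.23. The integrin beta 3 gene Itgb3 (chromosome 11, 104608000 to 104670471) was at 452 ± 40.9 CPM in WT and 286 ± 47.1 CPM (SD, n = 2), a log2 fold change of -0.65 ± 0.17 (SE). It was the only member to pass when adjusted over the list alone (adjusted p = 0.0445, edgeR quasi-likelihood test), and none passed over all genes. Clusterin, Clu, had a log2 fold change of -0.84 ± 0.36 and the chemotactic receptor Gpr183 of -0.76 ± 0.36 (SE). The Clu value was -1.41 without p53R248W/+ replicate 1 and -0.47 without p53R248W/+ replicate 2. Vwf and Selp, which mark platelet-biased stem cells, were at -0.04 ± 0.16 and -0.39 ± 0.25 (SE); the Vwf value turned with single libraries left out, the Selp value ran from -0.91 to -0.03, and Selp shares 438 exon bases with Gm16548. The adjusted camera p was 0.00357, against an adjusted p of 0.657 with an estimated correlation. The call was lost without p53R248W/+ replicate 2: the median was -0.08 (adjusted p = 0.711) without it, -0.49 without p53R248W/+ replicate 1, -0.14 without WT replicate 1 and -0.11 without WT replicate 2.

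Marker lists of B cells with plasma cells and of mast cells with basophils were the 2 lists higher in p53R248W/+ cells, and their members were mostly at low levels. Of 11 tested B cell and plasma cell genes, 10 were higher, with a median log2 fold change of 1.18. Blnk, an adaptor of the B cell receptor, was at 1.39 and 2.38 CPM in WT against 18.3 and 5.70 CPM, and its log2 fold change of 2.73 ± 0.92 (SE) was 1.59 without p53R248W/+ replicate 1. Of 11 tested mast cell and basophil genes, 9 were higher, with a median of 0.40. The list as fixed also held eosinophil genes, and Gzmb, which is in the T and NK cell list too. Its call is therefore not particular to mast cells or basophils. The basophil protease Mcpt8 was at 0.837 and 1.82 CPM in WT against 2.83 and 13.2 CPM. The eosinophil genes Ear1, which has close paralogs, and Epx had 1 and 2 counts in WT replicate 1, under the 3-count floor, so no fold is given. Ear1 was at 1.96 CPM in WT replicate 2 against 10.5 and 9.17 CPM, and Epx at 0.701 CPM against 1.96 and 6.69 CPM. Cpa3, an abundant mast cell protease, was at 15.4 to 27.4 CPM in all libraries. No member passed, over all genes or when adjusted over the list alone. The adjusted camera p was 0.0278 for the B cell list and 0.0208 for the mast cell list, and the adjusted p was 0.657 for both with an estimated correlation. The B cell list was lost without WT replicate 2 (adjusted p = 0.127, median 1.12) or p53R248W/+ replicate 1 (0.414, median 0.81), and its median was 0.76 with the stricter filter. The mast cell list was lost without WT replicate 2 (0.247, median 0.19) or p53R248W/+ replicate 2 (0.523, median 0.21), and its median was 1.15 without WT replicate 1 and 0.63 without p53R248W/+ replicate 1.

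The remaining 16 lists did not pass camera over all 4 libraries, at adjusted p of 0.0506 to 0.648. The lymphoid priming genes came nearest, with a median of 0.21 and an adjusted p of 0.0506, and Dntt passed when adjusted over the list alone (adjusted p = 0.0152, edgeR quasi-likelihood test). The lymphoid priming list passed without WT replicate 1 (median 0.25, adjusted p = 0.0334), without p53R248W/+ replicate 1 (0.38, 0.00308), with the stricter filter (0.18, 0.0459) and with the replicate number as a block (0.21, 0.0482). Its median was -0.08 without p53R248W/+ replicate 2 (adjusted p = 0.789). Among megakaryocyte and platelet genes (median -0.03), Itgb3 and the integrin alpha IIb gene Itga2b passed when adjusted over the list alone (adjusted p = 0.0155 for both, edgeR quasi-likelihood test). Itga2b was at 74.8 ± 13.7 CPM in WT and 30.7 ± 4.22 CPM (SD, n = 2). Median log2 fold changes were 0.19 for stem cell identity genes, -0.34 for erythroid genes, 0.15 for granulocyte and monocyte genes, 0.07 for T and NK cell genes and 0.42 for endothelial and stromal genes. They were 0.03 for type I interferon response genes, -0.05 for NF-kB and inflammatory genes, 0.16 for inflammasome and pyroptosis genes and -0.07 for MHC class II genes. They were 0.02 for chromatin regulators, 0.00093 for splicing factors, -0.11 for DNA repair genes, -0.09 for apoptosis regulators and -0.08 for cytosolic ribosomal protein genes. The MHC class II list passed in opposite directions, lower without WT replicate 1 (median -0.71, adjusted p = 0.0120) and higher without WT replicate 2 (1.37, 0.00121). Endothelial and stromal genes passed as higher without WT replicate 1 (0.88, 0.0309) and with the stricter filter (0.70, 0.0279), and inflammasome genes as higher with the stricter filter (0.17, 0.0420). Ribosomal protein genes passed as lower without WT replicate 2 (-0.18, 0.00121), without p53R248W/+ replicate 1 (-0.14, 0.00556) and with the block (-0.09, 0.0482). NF-kB genes passed as lower without WT replicate 2 (-0.23, 0.0288) and without p53R248W/+ replicate 2 (-0.34, 0.0424). Stem cell identity genes passed as higher without p53R248W/+ replicate 2 (0.26, 0.00405) and had a median of -0.11 without p53R248W/+ replicate 1 (0.414). The erythroid median was 0.20 with the stricter filter, 0.012 without WT replicate 2, 0.10 without p53R248W/+ replicate 1 and -0.57 without p53R248W/+ replicate 2. The interferon median was 0.30 without WT replicate 2, 0.14 without p53R248W/+ replicate 1 and -0.084 without p53R248W/+ replicate 2, and the list passed in none of these fits (adjusted p of 0.0659 to 0.709). For the megakaryocyte, endothelial, MHC class II, chromatin and splicing lists, the median, the mean and the direction of the test did not all have the same sign.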

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

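The p53 target list without Cdkn1a and Btg2 (median -0.18, adjusted p = 0.125 with limma's camera) was the only alternative chosen after the data were seen. The count of genes past the threshold stayed at 0 under median-ratio and total-count scaling, legacy quasi-likelihood, robust=FALSE, no filter, the stricter filter, limma-voom and the replicate block. The likelihood ratio test of edgeR called 4 genes and DESeq2 called 7, and leaving out a library gave 0 to 1 genes. The single call was Usp33, without p53R248W/+ replicate 2. The cause of these differences was not tested. DESeq2 also called Cdkn1a (adjusted p = 0.0348) and Il1rl1 (adjusted p = 0.0269), which no other setting called. The adjusted p of Cdkn1a ranged from 0.0348 to 0.999 over the alternatives, and its log2 fold change from -2.19 to -1.30. A lone library of a genotype was assumed to vary like the other genotype.

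Camera with the preset correlation called 10 lists, 12 with the replicate block, 11 with the stricter filter and 6 to 11 when a library was left out, the fewest without p53R248W/+ replicate 1. These counts include lists outside the 10. An estimated correlation and fry each called 0. The median of the immediate early and stress list ranged from -0.86 to -0.45 over 9 camera settings and passed in each. Legacy quasi-likelihood and robust=FALSE do not enter camera, and the other tools were not run on the lists. The Trp53 log2 fold change ranged from -0.44 to 0.0023 with a library left out. The Mdm2 value turned to 0.11 without WT replicate 1 and ranged from -0.27 to 0.13 over the 4 fits, the Ccng1 value from -0.16 to 0.23 and the mitosis median from -0.82 to 0.12, each turning without p53R248W/+ replicate 1. The Vwf value ranged from -0.24 to 0.12. Of 767 values of single named genes over the alternatives, 754 kept their direction and side of the threshold, 6 turned and 7 newly passed. Most of these genes were chosen because the genotypes did not overlap, which largely fixed their direction when a library was left out. No gene passed in the main fit, so keeping its side of the threshold meant not passing again. These counts are therefore no measure of stability. Among lists that did not pass, the direction of the test turned with a library left out for the lists that follow, given with the range of their medians: -0.11 to 0.26 for stem cell identity, -0.27 to 0.15 for megakaryocyte, -0.21 to 0.36 for granulocyte, 0.048 to 0.55 for T and NK cell, -0.71 to 1.37 for MHC class II, -0.00012 to 0.090 for chromatin, -0.091 to 0.025 for splicing, -0.27 to 0.091 for DNA repair and -0.18 to 0.032 for ribosomal protein genes. The other lists that did not pass ranged from -0.57 to 0.10 for erythroid, -0.084 to 0.30 for interferon, -0.075 to 0.38 for lymphoid priming, -0.34 to -0.048 for NF-kB, 0.029 to 0.14 for inflammasome, 0.15 to 0.88 for endothelial and -0.27 to -0.0024 for apoptosis genes. With the stricter filter the medians of the erythroid and granulocyte lists turned to 0.20 and -0.087. The mast cell list had too few members under the stricter filter. The series' design text calls the sequencing paired without saying whether reads or animals are meant, and no label ties equal replicate numbers to a shared animal or day. The deviations of replicate 1 from its genotype mean correlated at r = -0.0074 between genotypes, over genes, so the numbers were not taken to pair the samples, and pairing by animal cannot be ruled out. Depth limited the low genes: 3 counts corresponded to 0.202 to 0.248 CPM.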

Other observations

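Several single genes outside the lists that passed had the same direction in both libraries of a genotype, at values that did not pass over all genes (adjusted p = 0.824 with edgeR's quasi-likelihood test for the genes named in this paragraph). They were picked after their values were seen, and 33.6% of all tested genes did not overlap between genotypes, where chance gives 33.3%. They therefore stand as values only. Their lists often differed from them: 24 of 36 stem cell identity genes were higher, unlike Hoxb5. The medians were 0.03 for interferon genes and 0.02 for chromatin genes, of which 10 of 45 were separated as higher and 6 as lower. Gata1, the master regulator of erythroid and megakaryocytic fate, was at 6.76 and 5.54 CPM in WT and at 0.809 CPM in p53R248W/+ replicate 1, and had 2 counts, under the 3-count floor, in p53R248W/+ replicate 2. Hoxb5, a marker of long-term stem cells, was at 44.4 and 16.7 CPM in WT against 13.2 and 13.5 CPM, a log2 fold change of -1.20 that was -0.32 without WT replicate 1. Pecam1 was at 70.4 and 50.7 CPM in WT against 105 and 100.4 CPM in p53R248W/+. The cytokine receptors Il18r1 and Il1r1 were higher, at 9.42 and 18.2 against 20.1 and 68.2 CPM and at 86.3 and 67.1 against 96.5 and 162 CPM. Their log2 fold changes were 0.54 and 0.33 without p53R248W/+ replicate 2. Among interferon response genes Irf7 was at 11.5 and 4.42 CPM in WT against 24.1 and 15.4 CPM in p53R248W/+. Kdm5b, a histone demethylase, was at 163 and 181 CPM in WT against 264 and 221 CPM, and Dnmt3a, a DNA methyltransferase, at 206 and 206 against 260 and 277 CPM. Usp33 was at 99.4 and 97.4 CPM in WT but at 502 and 179 CPM in the p53R248W/+ libraries, and its log2 fold change was 0.86 without p53R248W/+ replicate 1.

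Tests on the length and GC trend, on p53R248W/+ replicate 1, on captured molecules, on abundant genes and on the count of genes in other splits were set out before their results were seen; those on WT replicate 1, on handling, on the parts of the replication and energy pattern and on the list median in other splits were chosen after. The immediate early and stress genes were lower in p53R248W/+ cells by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.657, limma) or by fry (adjusted p = 0.646, limma). The shift did not rest on WT replicate 1 alone, since the median without that library was -0.453 (SE 0.0825). Median deviations of the members were 0.55 and 0.10 in WT replicates 1 and 2 and -0.44 and -0.21 in p53R248W/+. Both replicates 1 thus lay at the ends, and their joint part in the shift was not tested. A trend on gene length and GC content is argued against as the cause, since the median was -0.629 (SE 0.0788) with the trend removed. The trend itself was no lower than -0.099 for any gene. SEs of list medians in this section are over genes, which are not independent, so they do not measure the spread between libraries. Handling before lysis could move 29 of 30 members one way, and it cannot be told apart from genotype, because the labels record no sort day or time to lysis. Only 1 of the 3 splits of the 4 libraries, the real one, gave a median as far from 0. The real size was 0.668 and the highest other 0.353, and 3 splits are too few for a share under 0.05. The list was singled out by its shift in the real split, so this order was largely fixed in advance. The order is therefore no evidence for a genotype effect. In the mitosis list, median deviations in both replicates 1 (WT -0.18, p53R248W/+ -0.64) lay below those in both replicates 2 (0.49 and 0.36). A genotype effect remains open and untested.

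Replication, mitosis, histone and energy genes had a pooled median of -0.30 (SE 0.0335) over 186 genes. It was -0.57 without p53R248W/+ replicate 2 and -0.125 (SE 0.0525) without p53R248W/+ replicate 1. The value of -0.125 fell between the bounds set out in advance, so the pooled test could not decide on p53R248W/+ replicate 1 alone. The SEs are again over genes, whose estimated correlation was 0.30 in the replication list and 0.60 in the mitosis list. The length and GC trend is argued against as the cause, since the pooled median was -0.293 (SE 0.0377) with it removed and the trend, at 1.26% of the deviance, ran only from -0.099 to 0.31 over genes. For the histone and energy lists, the median over 106 genes was -0.274 (SE 0.0682) without p53R248W/+ replicate 1 against -0.30 over all libraries. The median of these lists thus did not rest on that library alone. This split into parts was chosen after the values were seen, so it does not replace the undecided pooled test. For the 80 replication and mitosis genes the median was -0.008 (SE 0.0458) without p53R248W/+ replicate 1 but also -0.072 without WT replicate 2. Mitosis genes lay at -0.18 and 0.49 in WT replicates 1 and 2 and at -0.64 and 0.36 in p53R248W/+. They were lower in replicate 1 than in replicate 2 in both genotypes. Replication genes lay at 0.12 and 0.26 in WT and at -0.43 and 0.10 in p53R248W/+. The replication median was -0.22 without WT replicate 2. With the replicate number as a block the medians were -0.29 for replication and -0.27 for mitosis. Over the 80 genes, p53R248W/+ replicate 1 alone cannot be told apart from a spread between single libraries of both genotypes. A share of cycling cells that varied between libraries and a genotype effect stay open and untested.

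The spread between libraries of a genotype was wide for their depth. The variance between the 2 libraries over the mean count was 25.9 in the lowest of 20 bins of genes and 114 in the highest in WT, and 24.8 and 96.1 in p53R248W/+, where reads alone give 1. In a fit with a constant term and a term that grows with the mean, the constant was 28.1 in WT (95% interval 26.5 to 29.8) and 27.9 in p53R248W/+ (26.3 to 29.7). The constant was above the bound set out in advance for few captured molecules, but differences between animals or preparations enter the same spread, so these cannot be told apart. A few genes taking most of the counts is argued against, since the 10 most abundant genes held no more than 6.96% of any library.

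The number of genes at an unadjusted p under 0.05 was 780 for the genotypes and 792 for the split that set both replicates 1 against both replicates 2. Thus 2 of the 3 splits gave as many genes as the real one, and 3 splits are too few for a share under 0.05.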
